A study of Mus musculus with 12 samples.

How the data were processed

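RNA came from the triceps brachii of male C57BL/6J mice of 12 weeks that received saline or 20-hydroxyecdysone (20E, an insect moulting steroid also made by plants) at 5 mg/kg/day from implanted osmotic pumps for 5 or 15 days. Per the labels, RNA of 3 animals was pooled in equal amounts for each array, except 1 saline pool with 2 animals, and 3 pools per group were hybridised to Illumina mouse whole-genome beadchips, giving 12 arrays. A p-value here therefore measures the spread between pools, which is narrower than the spread between animals.

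The deposited table of raw values holds, per the file headers, an average intensity for each of 45281 probes on each array, not normalized between arrays. The same deposited table gives a detection p-value per probe and array against the negative control beads. The authors' second table holds log2 values, which by their own distributions were background subtracted, quantile normalized and set to a floor of -1. BeadStudio 3.1.3 and limma are named in the submitters' processing notes, and the order of the steps is not given in the sources used here. In that table every array had a median of 2.91 and between 33.8% and 36.4% of probes lay at the floor.

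Columns of the raw table carry letters for treatment, a letter A or B and a replicate number. A was read as 5 days and B as 15 days, a reading that no label states outright. Under it, the pattern of each raw column across arrays correlated at 0.951 to 0.969 with its own column in the log2 table and at most 0.594 with any other. The columns also carry a number from 1 to 12, read here as an array number, which no label states. No beadchip is named in the sources used here, so the beadchip could not be used as a block, and arrays 1 to 6 against 7 to 12 were tried instead after the data were examined.

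Raw intensities were corrected and normalized with neqc of limma 3.58.1 in R 4.3.3, with negative controls inferred from the detection p-values, an offset of 16 and quantile normalization. Probes with a detection p under 0.05 on at least 3 arrays were kept, which left 19704. The number of arrays limits the precision. A linear model with 4 group means was fitted to all 12 arrays with lmFit and eBayes, with 8 residual and 2.89 prior degrees of freedom and a median residual SD of 0.179 log2 units, and p-values were adjusted by Benjamini-Hochberg within each contrast. Errors given with a difference are standard errors of the moderated fit.

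The platform annotation gave 1 gene symbol for 34885 probes, several for 18 and none for 10378; no gene was named from the last 2 kinds. Gene lists were tested with camera on 10696 genes, each represented by its probe with the highest mean, with a preset correlation of 0.01 between genes and adjustment over 42 lists (29 pathways and 13 cell types) fixed before the data were examined. Camera with an estimated correlation and fry were alternatives. Fixed in the same way were 6 contrasts, 20E against saline at each time and over both, their difference, and 15 against 5 days under each treatment.

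After none of the 6 contrasts gave a probe past the threshold, a further one was added, 15 against 5 days averaged over both treatments. The hepatocyte list, also added, was written after the arrays were seen and liver transcripts had been noticed among the leading genes of a principal component, so its own values are a description and not a test. Other alternatives added after the data were examined left out 5 arrays high in liver or lymphocyte genes, or took the scores of these gene groups as covariates. Without the 5 arrays, saline at 15 days holds 1 array, replicate 3, and each other group holds 2. The lone array is then assumed to vary like the other groups.

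Named genes followed a rule fixed before the data were examined: in each direction the passing probes with the largest change, 8 for the treatment contrasts and 5 for the others, filled up by the smallest unadjusted p among probes whose pools did not overlap (a requirement that has no meaning for the interaction); up to 4 leading members of each list past the threshold; and a set of muscle and steroid genes. For the added contrast 8 were taken. Clone names and probes without a single symbol were left out. Of the fixed genes, Mstn, Akt1 and Esr2 did not pass the detection filter.

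The fit was tested on data simulated from the real probe means and spreads with 200 changed probes. The 70 measured oxidative phosphorylation genes were also raised by 0.3 log2 units, and the shares below leave them out. For 20E against saline at 5 days, 27.0% of probes changed by 0.5 log2 units were called among 19704 tested, 82.0% at 1, 89.2% at 1.5 and 96.8% at 2. At 15 days the shares were 31.7%, 79.4%, 92.3% and 95.6%. For 15 against 5 days over both treatments they were 57.8%, 92.0%, 97.2% and 97.6%. In 5 simulations there were 60 false calls among 1140 calls, which also count the calls of the raised list. Simulated probes were independent, unlike real ones, so differences shared by many probes of an array were absent. The shares hold for this number of changed probes and may not hold for the real data.

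Probe counts, and named genes other than those named only as members of a list, were computed again with normexp and an offset of 50, no background correction, cyclic loess, the authors' log2 values, no filter, and a filter of detection p under 0.01 on all 12 arrays. They were also computed with 1 probe per gene, trended and robust eBayes, array weights, no moderation, the compared groups alone, the replicate number as a block, and without each array. Gene lists were computed again with the same alternatives except 1 probe per gene, trended and robust eBayes, array weights and no moderation, and also with the mean of the probes of a gene. The correlation of the effects was not computed again under those exceptions, the mean of the probes, the compared groups alone or the random block. Python 3.11.15 with matplotlib 3.10.9 drew the figures.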

Results

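Gene expression was measured in triceps muscle of mice infused with saline or 20E for 5 or 15 days, to evaluate the effect of 20E on muscle. Each of the 4 groups held 3 arrays, each of a pool of animals. The arrays detected between 17106 and 18861 probes (37.8% to 41.7%), with median raw intensities of 111 to 140. Arrays numbered 1 to 6 had medians of 123 to 140 and those numbered 7 to 12 medians of 111 to 118. No arrays were identical, and correlations between arrays ran from 0.965 to 0.994, with a median of 0.986 within groups and 0.986 between groups.

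Transcripts of other tissues set some pools apart. Lymphocyte genes, such as the B cell receptor component Cd79b, lay above their mean over all arrays by 3.44 log2 units in saline 5 d replicate 2 and by 2.29 in 20E 5 d replicate 3. Hepatocyte genes, such as the plasma protein genes Apoa1 and Ttr, lay above theirs by 3.39 in saline 15 d replicate 1, by 3.39 in 20E 15 d replicate 3 and by 1.01 in saline 15 d replicate 2. In 20E 5 d replicate 1 the values were 0.487 for lymphocyte and 0.309 for hepatocyte genes. The first 2 principal components held 34.9% and 21.6% of the variance.

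**Figure D1:**
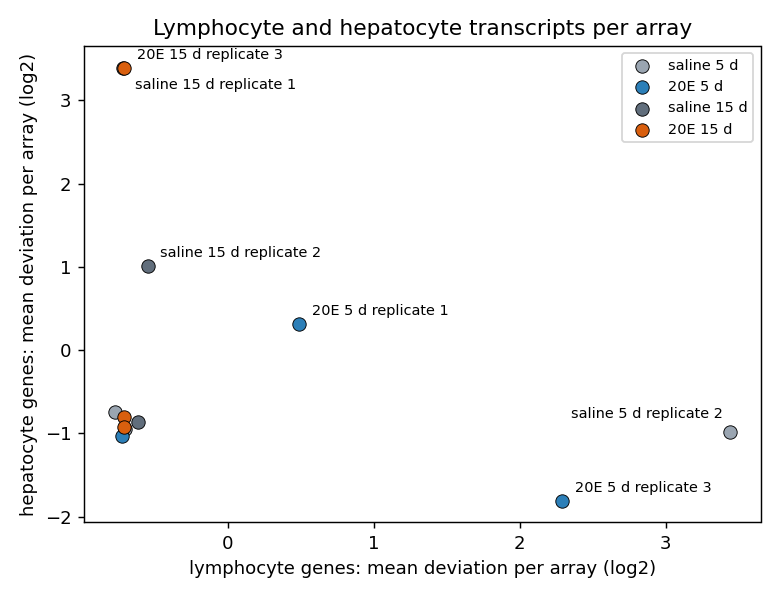
Each point is 1 array, placed by the mean deviation of its lymphocyte genes (x axis, log2) and of its hepatocyte genes (y axis, log2) from their mean over all 12 arrays, coloured by group; arrays above 0 on either axis are labelled. Hepatocyte values reach 3.39 in 1 saline and 1 20E array of 15 days, and lymphocyte values reach 3.44 in a saline and 2.29 in a 20E array of 5 days.

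After 5 days of infusion no probe differed between 20E and saline past the threshold in limma (0 of 19704). At an unadjusted p under 0.05 there were 684 probes, 372 higher and 312 lower, where 985 are expected by chance. The genes with the clearest separation that did not pass included Ghr, the growth hormone receptor, at 0.55 ± 0.12 log2 units (SE, n = 3 pools per group; adjusted p = 1), Cpeb2, a translational regulator, at 0.73 ± 0.15, and Pxdn, a matrix peroxidase, at 0.49 ± 0.10. On the lower side stood Gxylt1 at -0.69 ± 0.15, Pkp4 at -0.49 ± 0.11 and Prf1, perforin of cytotoxic lymphocytes, at -0.47 ± 0.11. The sizes depended on the processing. Over the alternatives Cpeb2 ran from 0.22 to 3.25, Pxdn from 0.15 to 2.69, Gxylt1 from -1.07 to -0.22 and Pkp4 from -0.99 to -0.14, each smallest without background correction and largest with the authors' values. Ghr ran from 0.35 to 0.64 and Prf1 from -0.55 to -0.40. Pools did not overlap for 802 probes in the higher and 601 in the lower direction, 4.07% and 3.05% of probes, where chance gives 5% each way.

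By camera with the preset correlation, 5 of 42 lists differed at 5 days, and with an estimated correlation 0 did. Slow fibre contractile genes were higher as a list, 17 of 17 members with a median of 0.34 log2 units (adjusted p = 7.67e-04, 0.987 with an estimated correlation). Among them were the troponin Tnni1 at 0.69 ± 0.35 and the myosin light chain Myl2 at 0.68 ± 0.41. Without saline 5 d replicate 3 this list's median was 0.017 and the test turned to the lower side (adjusted p = 0.905). Leaving out 20E 5 d replicate 3 gave an adjusted p of 0.0576. Adipocyte genes were higher in 12 of 13 members (median 0.53; adjusted p = 1.12e-04, 0.987 with an estimated correlation), with leptin, Lep, at 1.62 ± 0.66. Fatty acid and triglyceride synthesis genes were higher in 15 of 20 (median 0.17; adjusted p = 0.00773, 0.987 with an estimated correlation), with the elongase Elovl6 at 1.19 ± 0.52. Tendon genes were lower in 6 of 6 (median -0.45; adjusted p = 0.00213, 0.967 with an estimated correlation), and endothelial genes in 16 of 17 (median -0.12; adjusted p = 1.71e-04, 0.873 with an estimated correlation). Adjusted over the list alone, 0 members passed in each of these 5 lists. Without 20E 5 d replicate 1 the calls of the adipocyte list (median 0.10; adjusted p = 0.238), the triglyceride list (median 0.068; adjusted p = 0.73) and the tendon list (median -0.15; adjusted p = 0.129) were lost. The tendon call was also lost without the detection filter (median -0.077; adjusted p = 0.054). Without background correction the medians were 0.20 for adipocyte, 0.12 for triglyceride and -0.26 for tendon genes, and with normexp 0.30 for adipocyte genes. Without the 5 arrays high in liver or lymphocyte genes they were 0.89 for adipocyte and 0.27 for triglyceride genes. In that fit 20E 5 d replicate 1, without which both calls were lost, is 1 of 2 20E arrays of 5 days. It also had the highest lymphocyte and hepatocyte scores of the arrays kept, so the larger medians do not show a stronger effect. The endothelial median was -0.077 without 20E 5 d replicate 1, the triglyceride median 0.26 without 20E 5 d replicate 2 and the slow fibre median 0.54 without saline 5 d replicate 2.

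**Figure D2:**
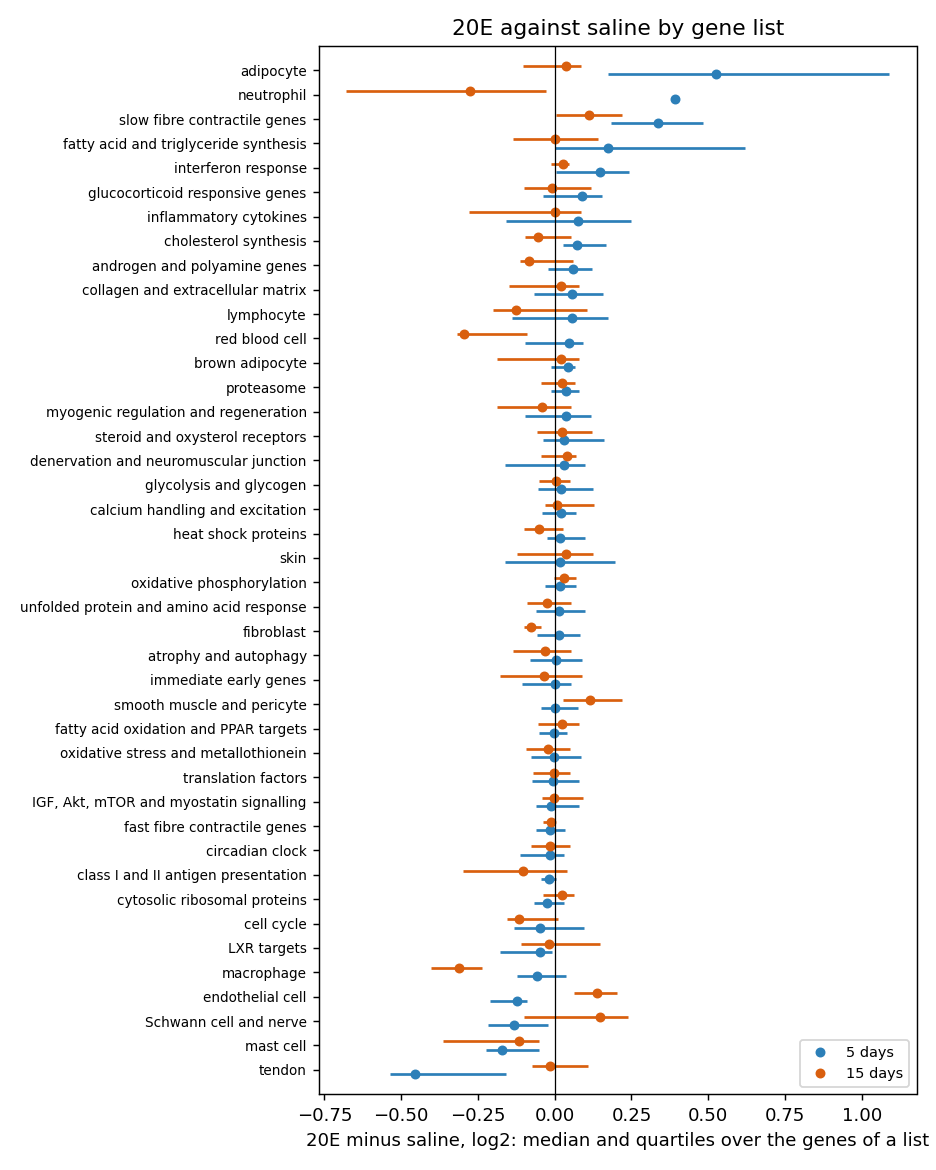
For each of the 42 gene lists, points give the median over its genes of the log2 difference between 20E and saline at 5 days (blue) and 15 days (orange), and lines give the quartiles over genes, not replicate error. Adipocyte genes lie at 0.53 and tendon genes at -0.45 at 5 days, and macrophage genes at -0.31 at 15 days.

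After 15 days no probe differed between 20E and saline in limma either (0 of 19704, smallest adjusted p = 0.761). There were 819 probes at an unadjusted p under 0.05, 480 higher and 339 lower. Values that did not pass included Tspan17, a tetraspanin, at 0.66 ± 0.10, Bmp6, a bone morphogenetic protein, at 0.51 ± 0.09 and Usp9x, a deubiquitinase, at 0.53 ± 0.11. Cma1, a chymase of mast cells, stood at -0.74 ± 0.14 and B3galnt1 at -0.81 ± 0.19. Over the alternatives Tspan17 ran from 0.21 to 4.39, Bmp6 from 0.14 to 0.86, Cma1 from -1.81 to -0.21 and B3galnt1 from -3.0 to -0.28, again smallest without background correction and largest with the authors' values. Usp9x ran from 0.25 to 0.65. Macrophage genes were lower as a list, 17 of 17 members with a median of -0.31 (adjusted p = 1.4e-05, 0.965 with an estimated correlation). Its members included the Fc receptor Fcgr3 at -0.50 ± 0.19 and the growth factor receptor Csf1r at -0.27 ± 0.15. The median was -0.17 without background correction and -0.20 with normexp. Endothelial genes were higher in 15 of 17 (median 0.14; adjusted p = 0.00385, 0.896 with an estimated correlation). This call was lost without 20E 15 d replicate 2 (adjusted p = 0.106), saline 15 d replicate 1 (adjusted p = 0.0692) or saline 15 d replicate 2 (adjusted p = 0.115). It was also lost without the 5 arrays high in liver or lymphocyte genes (median 0.035; adjusted p = 0.536), where saline 15 d replicate 3 is the only saline array of 15 days. Adjusted over the list alone, 0 members of either list passed. Hepatocyte genes were lower in 18 of 19 members with a median of -0.61 in the same comparison. Pools did not overlap for 1088 probes in the higher and 928 in the lower direction, 5.52% and 4.71%.

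Averaged over both times, 0 of 19704 probes differed (smallest adjusted p = 0.86), with 823 at an unadjusted p under 0.05. Values that did not pass included Atpaf1, an assembly factor of the mitochondrial ATP synthase, at 0.51 ± 0.08, Sass6, a centriole protein, at 0.51 ± 0.08, Hif1a, the hypoxia-inducible factor, at -0.56 ± 0.12 and Cma1 at -0.49 ± 0.10. Over the alternatives these ran from 0.14 to 1.05 for Atpaf1, 0.14 to 0.93 for Sass6, -0.96 to -0.17 for Hif1a and -1.16 to -0.14 for Cma1. The fixed muscle genes lay near 0: Fbxo32 and Trim63, ubiquitin ligases of muscle atrophy, at -0.11 ± 0.20 and -0.07 ± 0.07, Igf1, a growth factor, at -0.07 ± 0.14, the fast myosin Myh4 at -0.01 ± 0.08 and the myogenic factor Myod1 at 0.17 ± 0.12. Fbxo32 ran from -0.46 without the 5 arrays to 0.059 without saline 15 d replicate 3. The slow myosin Myh7 was at 0.35 ± 0.30 and Ppargc1a, a regulator of mitochondrial genes, at -0.27 ± 0.16. Without saline 5 d replicate 3 Myh7 was at 0.040, and without the 5 arrays at 0.58. Ppargc1a ran from -0.39 to -0.13. Past the preset camera test were slow fibre genes (17 of 17 higher, median 0.18; adjusted p = 0.00884), adipocyte genes (10 of 13 higher, median 0.32; adjusted p = 0.0128) and macrophage genes (17 of 17 lower, median -0.18; adjusted p = 0.00114). The adipocyte median was 0.14 without background correction, 0.19 with normexp and 0.48 without the 5 arrays. In the last fit 20E 5 d replicate 1 is 1 of 2 20E arrays of 5 days. The macrophage median was -0.105 without background correction and -0.30 with the array number as a block. With an estimated correlation each of these 3 had an adjusted p = 0.986, and adjusted over the list alone 0 members passed. The slow fibre call was lost without 20E 5 d replicate 1 (adjusted p = 0.0673), 20E 5 d replicate 3 (adjusted p = 0.0895), saline 5 d replicate 3 (median 0.040; adjusted p = 0.341) or saline 15 d replicate 1 (median 0.12; adjusted p = 0.18), and the median was 0.29 without saline 5 d replicate 1. It was also lost with the array number as a block (median 0.15; adjusted p = 0.191). The macrophage call was lost without saline 5 d replicate 2 (median -0.049; adjusted p = 0.573), and its median was -0.28 without saline 5 d replicate 3. The adipocyte call was lost without 20E 5 d replicate 1 (median 0.15; adjusted p = 0.4), saline 5 d replicate 3 (adjusted p = 0.0716), 20E 15 d replicate 1 (adjusted p = 0.103), saline 15 d replicate 3 (adjusted p = 0.0761) or saline 15 d replicate 2 (adjusted p = 0.0562). With the first 6 and the last 6 arrays as a block, 0 probes passed in each of these treatment contrasts. Within the first 6 arrays alone 6 probes passed at 5 days and 0 at 15 days, and within the last 6 arrays 0 at both, with 2 residual degrees of freedom. The first 6 hold 1 20E array per time and the last 6 hold 1 saline array per time, so each of these comparisons rests on a lone array assumed to vary like the others.

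The difference between the 20E effects at 15 and 5 days was tested as an interaction, which gave 0 of 19704 probes and 664 at an unadjusted p under 0.05. Endothelial genes moved apart as a list, 16 of 17 more positive at 15 days with a median difference of 0.27 (adjusted p = 2.17e-07, 0.232 with an estimated correlation). They included Pecam1 at 0.47 ± 0.20 and the transcription factor Sox17 at 0.42 ± 0.18. Adipocyte genes were more negative in 13 of 13 (median -0.42; adjusted p = 0.0114, 0.931 with an estimated correlation), macrophage genes in 16 of 17 (median -0.27; adjusted p = 0.0174, 0.977 with an estimated correlation) and neutrophil genes in 4 of 5 (median -0.67; adjusted p = 0.0124, 0.83 with an estimated correlation). Lcn2, lipocalin of neutrophils, stood at -1.41 ± 0.38. Adjusted over the list alone, 1 neutrophil gene passed and 0 members of the other 3 lists did. The endothelial call held in 12 of 12 fits without 1 array. The macrophage call held in 5 of 12. It was lost without 20E 5 d replicate 3 (median -0.14; adjusted p = 0.425), saline 5 d replicate 1 (median -0.17; adjusted p = 0.226), saline 5 d replicate 3 (median -0.12; adjusted p = 0.435), 20E 15 d replicate 2 (adjusted p = 0.129), 20E 15 d replicate 3 (adjusted p = 0.0505), saline 15 d replicate 3 (adjusted p = 0.183) or saline 15 d replicate 2 (adjusted p = 0.0863). With the strict filter it was lost too (adjusted p = 0.196), and without saline 5 d replicate 2 its median was -0.55. The neutrophil call was lost without 20E 5 d replicate 3 (adjusted p = 0.0562), saline 5 d replicate 3 (median -0.38; adjusted p = 0.114), 20E 15 d replicate 2 (adjusted p = 0.175) or saline 15 d replicate 2 (adjusted p = 0.0545). It was also lost without the detection filter (median -0.0019; adjusted p = 0.483). The adipocyte call was lost without 20E 5 d replicate 1 (median -0.081; adjusted p = 0.507), saline 5 d replicate 3 (median -0.26; adjusted p = 0.09) or 20E 15 d replicate 2 (median -0.27; adjusted p = 0.129). Without background correction the medians were -0.13 for adipocyte, -0.14 for macrophage and -0.24 for neutrophil genes, and with the authors' values -2.09 for neutrophil genes. With normexp they were -0.21 for adipocyte and -0.38 for neutrophil genes. In the fit without the 5 arrays they were -0.83 for adipocyte, -0.56 for macrophage and -1.18 for neutrophil genes, with 1 saline array of 15 days left. There 20E 5 d replicate 1 is 1 of 2 20E arrays of 5 days. Across 10696 genes, which are not independent replicates, the 5 day and 15 day effects correlated at Pearson r = 0.0373 (exact permutation p = 0.83, two-sided, 400 relabellings) and Spearman rho = 0.0646 (exact permutation p = 0.43).

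More probes differed between 15 and 5 days than between 20E and saline, 2478 against 823 at an unadjusted p under 0.05 in limma. The pools high in lymphocyte genes were all of 5 days and those high in hepatocyte genes all of 15 days. Each kind occurred under both treatments. The larger count therefore does not separate the time since pump implantation from transcripts of other tissues. In the contrast over both treatments, added after the 6 planned contrasts gave 0 probes, 8 of 19704 probes passed in limma, 5 higher and 3 lower at 15 days. Actc1, the cardiac actin of developing muscle, rose by 0.97 ± 0.09 log2 units (adjusted p = 0.00769) and passed with both of its probes. Myod1 rose by 0.83 ± 0.12 (adjusted p = 0.0495) and G0s2, an inhibitor of fat breakdown, by 1.34 ± 0.18 (adjusted p = 0.0491), and 1 probe without a gene symbol rose by 0.47 ± 0.06 (adjusted p = 0.0451). Ciart, a repressor in the circadian clock, fell by 1.30 ± 0.14 (adjusted p = 0.00877) and passed with all 3 of its probes. Of 27 alternative fits, Actc1 passed in 25 and Ciart in 24 with 1 probe each, but G0s2 in only 8 and Myod1 in only 7. The count depended on the processing, from 0 to 91 probes, and was 0 both without the 5 arrays high in liver or lymphocyte genes and with these scores as covariates. It was 3 without 20E 5 d replicate 2, and 4 without 20E 5 d replicate 3, saline 5 d replicates 1 or 2, any 20E array of 15 days, or saline 15 d replicates 1 or 3. In the 7 arrays left, with 1 saline array of 15 days, Actc1 stood at 0.93 ± 0.14, Myod1 at 0.67 ± 0.14 and Ciart at -1.14 ± 0.22. Without background correction Myod1 stood at 0.56 and Ciart at -0.78.

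**Figure D3:**
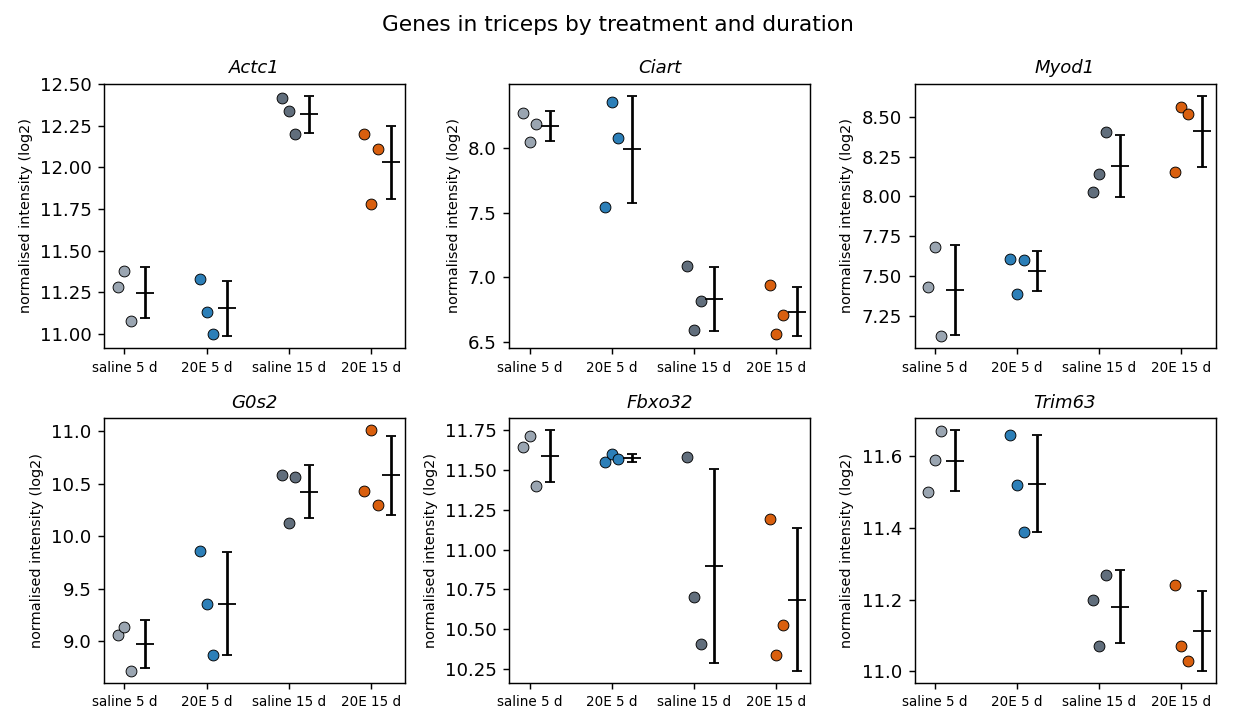
Normalised log2 intensity of 6 genes in each pool (points) by treatment and duration, with the mean and SD of the 3 pools beside them; the y axes do not start at 0. Actc1, Myod1 and G0s2 lie higher and Ciart and Trim63 lower in all 15 day pools than in all 5 day pools, while Fbxo32 overlaps between the times.

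Genes of energy metabolism and protein breakdown moved between the times as lists. Camera with the preset correlation passed 14 of 42 lists. Fatty acid oxidation genes were higher (median 0.10), a call that held in only 7 of 12 fits without 1 array. Proteasome genes were lower (median -0.07), which held in 12 of 12. Ribosomal, adipocyte, interferon and macrophage genes also passed as lower. With an estimated correlation or fry the calls of the fatty acid, proteasome, ribosomal, adipocyte, interferon and macrophage lists were lost. Oxidative phosphorylation genes were higher at 15 days in 66 of 70 members with a median of 0.10 (adjusted p = 5.68e-11, 0.042 with an estimated correlation). Examples were the ATP synthase subunit Atp5pb at 0.20 ± 0.05 and the complex I subunit Ndufa8 at 0.24 ± 0.06. Atrophy and autophagy genes were lower in 20 of 26 (median -0.10; adjusted p = 5.46e-04, 0.0485 with an estimated correlation). Fbxo32 stood at -0.79 ± 0.20 and Trim63 at -0.41 ± 0.07, neither past the threshold over all probes (adjusted p = 0.181 and 0.105). Without the 5 arrays high in liver or lymphocyte genes Fbxo32 stood at -0.45. Adjusted over the list alone, 3 and 4 members of these lists passed. Clock genes were lower in 13 of 15 (median -0.18; adjusted p = 3.56e-05, 0.0893 with an estimated correlation). Adjusted over the list alone, 8 of the 15 passed, counted in either direction. Dbp stood at -0.39 ± 0.08, while Arntl was higher, at 0.65 ± 0.14. Without the detection filter the clock median was -0.12. Heat shock genes were higher in 19 of 23 (median 0.06; adjusted p = 4.81e-04, 0.308 with an estimated correlation), with the chaperones Hspa1a at 1.37 ± 0.20 (0.77 without background correction) and Dnajb1 at 0.86 ± 0.12. The heat shock median was 0.10 without the 5 arrays high in liver or lymphocyte genes and 0.10 with their scores as covariates. Glucocorticoid responsive genes were lower in 20 of 28 (median -0.21; adjusted p = 5.46e-04, 0.329 with an estimated correlation), with the cell cycle inhibitor Cdkn1a at -0.67 ± 0.13 and Pdk4 at -0.69 ± 0.17. That list shares Fbxo32, Trim63, Foxo1, Mt1 and Mt2 with the atrophy list and Per1 with the clock list. Their calls are therefore not independent.

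Immune genes were lower at 15 days beside the lymphocyte transcripts of 2 of the 5 day pools. Lymphocyte genes were lower in 9 of 9 members (median -1.47; adjusted p = 0.00125, 0.516 with an estimated correlation) and antigen presentation genes in 14 of 14 (median -0.49; adjusted p = 3.56e-05, 0.497 with an estimated correlation), with the class II gene H2-Aa at -1.31 ± 0.48. Without saline 5 d replicate 2 these medians were -0.69 and -0.25, and the lymphocyte median was -0.66 without background correction, -0.88 with normexp and -0.89 without the detection filter. The lymphocyte call was lost with the strict filter (adjusted p = 0.0967). It was also lost without the 5 arrays high in liver or lymphocyte genes (median -0.31) and with their scores as covariates (median -0.030, adjusted p = 0.998). The lymphocyte score is the mean of these same genes and helped pick the 5 arrays. These last 2 losses therefore decide nothing. The antigen presentation call was lost with the covariates (median -0.11; adjusted p = 0.0513), and without the 5 arrays the median was -0.15. Hepatocyte genes were higher in 19 of 19 with a median of 1.87. Endothelial genes were higher in 15 of 17 (median 0.12; adjusted p = 5.46e-04, 0.308 with an estimated correlation), with Eng at 0.32 ± 0.07. The endothelial median was 0.22 both without the 5 arrays and with the covariates.

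Within saline alone, 0 of 19704 probes differed between the times in limma (smallest adjusted p = 0.0698, of Actc1 at 1.20 ± 0.14), with 1443 at an unadjusted p under 0.05. Within 20E alone 0 differed (smallest adjusted p = 0.105, of Ciart at -1.39 ± 0.17), with 1594. The preset camera test passed 12 lists in saline and 17 in 20E, and with an estimated correlation 0 and 2. Oxidative phosphorylation genes were higher in 63 of 70 members in saline (adjusted p = 9.69e-07, 0.172 with an estimated correlation) and in 65 of 70 in 20E (adjusted p = 8.17e-09, 0.0443 with an estimated correlation). Atrophy genes were lower in 19 of 26, with a median of -0.11, and in 17 of 26 (adjusted p = 0.0315 and 3.97e-04, and 0.214 and 0.0443 with an estimated correlation). In saline the atrophy call was lost without saline 5 d replicate 1 (adjusted p = 0.0597) or saline 5 d replicate 3 (median -0.058; adjusted p = 0.0974). Without the 5 arrays high in liver or lymphocyte genes the adjusted p was 0.0973 at a median of -0.11, about the same size, with 1 saline array of 15 days left. Without background correction the median was -0.068. Antigen presentation genes were lower in saline with a median of -0.47, and without saline 5 d replicate 2 the median was -0.015 and the test turned to the higher side (adjusted p = 0.734). Without the 5 arrays its median was 0.17 (adjusted p = 0.0843), a value of the 1 saline array of 15 days left against 2 of 5 days, and with the covariates the call was lost (median -0.073; adjusted p = 0.257).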

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

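Tests chosen only after their result was seen were those of liver RNA, of 20E and of duration as sources of the liver and lymphocyte transcripts, and of lymphoid tissue by the fixed list. So were those of the array numbers, of the clock phase and of Fbxo32 in saline, and the contrast of 15 against 5 days over both treatments was itself added then. The effect of 20E differed between the times, by the interaction test with a preset correlation, for 4 lists, with median differences of -0.42 for adipocyte, -0.266 for macrophage, -0.668 for neutrophil and 0.272 for endothelial genes. Without 20E 5 d replicate 1 the adipocyte median was -0.081. With an estimated correlation 0 of these passed. Of 100 splits of the arrays within each time, 74 gave at least the 4 lists of the real one, and the highest other gave 14, so chance is not excluded. For probes at an unadjusted p under 0.05, 79 of 100 gave at least the real 664, with 2429 as the highest other.

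For 20E against saline the other splits gave as much as the real one. Over both times, 56 of 100 splits gave at least 823 probes at an unadjusted p under 0.05 (highest other 2356) and 80 of 100 gave at least 3 lists (highest other 14), so chance is not excluded. At each time there are 10 splits, too few for a share under 0.05. At 5 days 8 of 10 reached the real 684 probes (highest other 2471) and 8 of 10 the real 5 lists (highest other 14). At 15 days 7 of 10 reached 819 (highest other 1160) and 5 of 10 reached 2 lists (highest other 4). The split with 2471 probes at 5 days, and that with 1160 at 15 days, part arrays 1 to 6 from arrays 7 to 12, and had 0 probes past the threshold. Another split parts the 3 pools highest in lymphocyte genes at 5 days, with 2447 probes at an unadjusted p under 0.05, 40 past the threshold and 12 lists. At 15 days the split of the 3 pools highest in hepatocyte genes had 1098, 75 and 3. These scores were compared with the splits after the counts were seen. Both point to a structure of the samples beside the groups, and its source is not settled between array number and transcripts of other tissues. With the array number as a block, 0 probes passed for 20E and 817 at 5 days and 956 at 15 days had an unadjusted p under 0.05.

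For 15 against 5 days over both treatments, 1 of 100 splits within treatments, the real one, gave 8 probes past the threshold (highest other 0) and 1 gave 2478 at an unadjusted p under 0.05 (highest other 1864). For its 14 lists the number was 4 of 100 (highest other 17). These shares lie under 0.05. The contrast itself was chosen after the data were examined, so they do not exclude chance. Within saline, 1 of 10 splits reached 1443 probes (highest other 1235) and 2 of 10 reached 12 lists (highest other 13). Within 20E, 1 of 10 reached 1594 probes (highest other 1176) and 1 of 10 reached 17 lists (highest other 12). These 10 splits are too few for a share under 0.05.

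Liver genes were high in 3 of the 15 day pools. Of 5 measured hepatocyte genes that had not been seen before the list was written, 100% lay over 1 log2 unit above the median of the other 9 arrays in 20E 15 d replicate 3 and in saline 15 d replicate 1, and 20.0% in saline 15 d replicate 2. Thus liver RNA in the pools is a candidate source, as a hypothesis. Apoa2, among the most abundant of these genes, reached 12.87 log2 units in 20E 15 d replicate 3 and 12.70 in saline 15 d replicate 1. Of the 19 measured hepatocyte genes, 14 were also detected on each of the 7 arrays with neither score above 1 log2 unit. 20E as the only source is argued against, as the highest saline pool, at 3.393, lay as high as the highest 20E pool, at 3.387. By the test set for it, the lowest 20E pool lay below the highest saline pool (-4.31 log2 units). That argues only against every 20E pool lying above every saline pool, so an effect in some pools stays open. A rise in muscle by 15 days stays open by the test set for it, as 0 of 6 pools of 15 days lay at or below the median of 5 days. A rise shared by all 15 day pools is argued against by a bound set after the values were seen, as 3 of 6 lay at or below the highest 5 day pool. A rise in some animals stays open.

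Lymphocyte genes were high in 2 of the 5 day pools. Each of the 9 measured genes of the fixed list (100%) lay over 1 log2 unit above the median of the other 10 arrays in both pools, but their mean had picked these pools, so this decides nothing. Of 16 measured lymphocyte genes outside that list, written down before their values were seen, 56.2% did so in each pool, between the bounds set for and against. Lymphoid tissue beside the muscle therefore stays open. Glycam1, outside the fixed list, reached 9.99 log2 units in saline 5 d replicate 2, 8.38 in 20E 5 d replicate 3 and 7.30 in 20E 5 d replicate 1. On the other arrays it lay between 4.32 and 4.57. As 1 gene it does not settle the source. Cd52 and Coro1a reached 11.66 and 11.55 log2 units in saline 5 d replicate 2, and 2 of the 9 were detected on each of the 7 arrays with neither score above 1 log2 unit. Of these 7, 20E 5 d replicate 1 had the highest scores, 0.487 for lymphocyte and 0.309 for hepatocyte genes. Its Cd79b and Cd52 values, 6.42 and 8.71 log2 units, also lay above those of the rest of these 7, so this pool was raised too. 20E as the only source is argued against, as the highest saline pool exceeded the highest 20E pool by 1.15 log2 units. Macrophage genes rose by at most 0.223 of the lymphocyte rise, below the bound set against inflammation led by macrophages. The pools had been picked by their lymphocyte mean, and few lymphocyte genes were detected on all those 7 arrays. A low ratio could thus arise under any cause, and this decides nothing.

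Ciart, Myod1 and Actc1 passed between 15 and 5 days over both treatments, and Fbxo32 did not. By the test set for liver or lymphoid RNA, 4 of 4 genes kept over 50% of the difference without the 5 arrays. Fbxo32 went from -0.79 ± 0.20 to -0.45 ± 0.20 and Ciart from -1.30 ± 0.14 to -1.14 ± 0.22. Myod1 went from 0.83 ± 0.12 to 0.67 ± 0.14 and Actc1 from 0.97 ± 0.09 to 0.93 ± 0.14. These values average in 1 saline array of 15 days, so for saline they decide nothing. No probe passed in the 7 arrays left (0 in limma, 1460 at an unadjusted p under 0.05), where each of these differences was smaller. In 20E, with 2 arrays left at each time, 4 of 4 kept over 50%. Ciart went from -1.26 to -1.2 there, Myod1 from 0.88 to 0.86 and Actc1 from 0.88 to 0.765. For Ciart, Myod1 and Actc1 in 20E this argues against liver or lymphoid RNA as the whole source. The arrays kept include 20E 5 d replicate 1, itself raised in lymphocyte genes, so a part stays open. In saline 3 of 4 kept over 50%, with 1 array left at 15 days. There Fbxo32 went from -0.68 to -0.09, a share of 0.137, and in 20E from -0.88 to -0.81. With the scores as covariates, on all arrays, it stood at -0.55 in saline. A single array decides nothing, so for Fbxo32 in saline liver or lymphoid RNA stays open. Blocking on the array number could not move these differences, since each set of 6 arrays holds as many 5 day as 15 day pools of each treatment. That 4 of 4 kept them with this block therefore decides nothing. Tissue taken at another phase of the clock may contribute, as a hypothesis. From 5 to 15 days the median change of the output genes, Dbp to Bhlhe41, lay 0.531 log2 units below that of Arntl and Clock (-0.531; exact permutation p = 0.005, two-sided, 400 relabellings). Ciart and the clock list had already stood out in this contrast, so this p-value is no separate support. Of the output genes, Ciart stood at -1.30, Nr1d1 at -0.44, Dbp at -0.39, Per1 at -0.38, Per3 at -0.33 and Nr1d2 at -0.15. Near 0 lay Bhlhe41 at -0.09 ± 0.10, Tef at -0.07 ± 0.10, Hlf at -0.07 ± 0.12 and Per2 at 0.02 ± 0.08. The opposite arm held only 2 genes, Arntl at 0.65 ± 0.14 and Clock at -0.07 ± 0.06. The hour of collection is not given in the sources used here, and recovery from surgery and age stay open and untested.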

How the results depend on the processing

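Leaving out the 5 arrays, taking their scores as covariates and blocking on the array number were chosen after the data were examined. Without the 5 arrays 1 saline array of 15 days is left, assumed to vary like the others. The treatment contrasts and the interaction had 0 probes under each alternative fitted to all arrays, without 1 array or without the 5 arrays. The fit within the first 6 arrays, with 1 20E array, gave 6 at 5 days. For 15 against 5 days over both treatments, 8 probes became 25 with normexp, 52 without background correction, 4 with the authors' values, 5 without a filter, 30 with the strict filter, and 2 with 1 probe per gene. It became 91 with trended and robust eBayes, 24 with array weights, 14 with the array number as a block, 0 without the 5 arrays and 0 with their scores as covariates. Leaving out 1 array gave 3 to 9, and 4 or fewer for 9 of the 12 arrays. In saline 0 became 2 with normexp, 2 without background correction, 2 with the strict filter, 4 with trended eBayes and 3 with the array number as a block (0 to 2 without 1 array, with 2 without 20E 5 d replicate 1 and 1 without saline 5 d replicate 3). In 20E 0 became 1 with the strict filter, 6 with trended eBayes and 1 with array weights (0 to 1, with 1 without 20E 5 d replicate 1). The cause was not tested, except that fewer arrays or probes entered some of these fits.

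Camera with an estimated correlation passed 0 lists in the 4 treatment contrasts. For 15 against 5 days it passed 0 in saline, 2 in 20E and 2 over both treatments. The fry test passed 0 in the 4 treatment contrasts, 3 in saline, 5 in 20E and 6 over both treatments. At 5 days 5 lists became 10 without the 5 arrays (4 to 14 without 1 array, with 14 without saline 5 d replicate 2 and 11 without saline 5 d replicate 3). At 15 days 2 became 5 with normexp, 5 without background correction and 7 without the 5 arrays (1 to 6, with 6 without 20E 15 d replicate 3, 4 without 20E 15 d replicate 1, and 1 without 20E 15 d replicate 2 or saline 15 d replicates 1 or 2). Over both times 3 became 6 with normexp, 6 without background correction, 6 with the strict filter, 7 with the array number as a block, 7 without the 5 arrays and 5 with the covariates (1 to 7, with 1 without 20E 5 d replicate 1, 7 without 20E 5 d replicate 2, 6 without saline 5 d replicate 1, and 5 without saline 5 d replicate 2, 20E 15 d replicate 3 or saline 15 d replicate 1). For the interaction 4 became 10 without the 5 arrays (1 to 10, with 10 without saline 5 d replicate 2, 1 without 20E 15 d replicate 2 and 2 without saline 15 d replicate 2). For 15 against 5 days the ranges without 1 array were 8 to 14 in saline, 9 to 18 in 20E, with 9 without 20E 5 d replicate 1, and 13 to 18 over both treatments. The correlation of the effects, 0.0373, became 0.168 with the array number as a block (-0.0452 to 0.126 without 1 array).

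Some list medians or tests turned. Without the 5 arrays, where saline at 15 days is replicate 3 alone, the medians in saline between times were 0.175 for antigen presentation, 0.038 for interferon and 0.179 for lymphocyte genes, and over both treatments -0.026 for macrophage genes. Without saline 5 d replicate 2 they were in saline -0.015, 0.053 and 0.128. With the covariates they were -0.029 for lymphocyte genes in 20E, -0.030 over both treatments, and 0.049 for macrophage genes. The lymphocyte covariate is the mean of the lymphocyte genes themselves, so their small medians were fixed in advance. Without saline 5 d replicate 3 slow fibre genes had -0.057 between times in saline and 0.017 for 20E at 5 days. Without 1 array, antigen presentation in saline ranged from -0.816 to -0.015, interferon from -0.284 to 0.053, lymphocyte genes from -2.12 to 0.128 and slow fibre genes from -0.057 to 0.570, and slow fibre genes for 20E at 5 days from 0.017 to 0.543. Of 147 named gene values, 67 were smallest without background correction and largest with the authors' values. Among 1573 list values, 7 had a median and a test of opposite sign.

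Replicate numbers did not pair the pools: same-numbered pools had correlations of deviations from -0.557 to 0.138, and 2 of 12 correlated best with their own number. With the replicate block 4 probes passed over both treatments, fixed or random, and 0 in the other contrasts. The beadchip as a block was not run, as no beadchip is named, and a fit of the compared groups alone is the full fit for the contrasts that use all 4 groups.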
